A study of Homo sapiens with 2 samples.

How the data were processed

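Whole-genome bisulfite sequencing was analysed for 2 libraries of HepG2, an established human hepatocellular carcinoma line. The control library came from cells without exposure to DEHP, di(2-ethylhexyl) phthalate, a plasticizer, and the DEHP library from exposed cells. The labels give neither dose nor duration. Each group holds 1 library, so no difference has a replicate check, and Fisher's exact tests on reads compare these libraries, not the conditions. Bisulfite turns unmethylated cytosine into a base read as thymine and leaves 5-methylcytosine and 5-hydroxymethylcytosine alike, so levels hold both.

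Per the labels, genomic DNA was sheared to 200-400 bp and built into libraries with the Accel-NGS Methyl-Seq kit, then read paired-end on an Illumina platform. The submitters' processing notes name FastQC 0.11.8, cutadapt 3.5, Trimmomatic 0.39, Bismark 0.24.0, Bowtie with no version, SAMtools 1.9 and the build GRCh38.p13, without the role or order of each. Whether duplicate reads were removed is not given in the sources used here. The deposited files give, per cytosine and strand, a count of methylated and a count of unmethylated reads. They also give the level as a deposited fraction, which equalled methylated over all reads at every cytosine to within 1e-06. The last deposited values are a p-value and its adjusted form. From the values, that p-value is an upper-tail binomial probability against 1 fixed background rate per context and library. The rate for CHH cytosines (H is A, C or T) was 0.394% in control and 0.395% in DEHP, and the cytosines it was measured on are not given in the sources used here.

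From the values, the files list only cytosines with at least 5 reads, at least 2 methylated reads for CpG (3 for CHG and CHH), a level of at least 5% and a small adjusted p-value. A cytosine that is missing from a file was unmethylated, methylated too little to be listed or too thinly covered, and these cannot be distinguished. A complete loss or gain of methylation in 1 library therefore removes a cytosine from the shared set, and levels of unmethylated regions, such as many CpG islands, are not measured here. Listed CpG cytosines numbered 31663802 in control (median depth 9 reads, 323297243 reads in all) and 34032904 in DEHP (median depth 10 reads, 375030097 reads). On chromosomes 1 to 22, X and Y, 27415397 were listed in both, 4171575 in control alone and 6533849 in DEHP alone.

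Levels were computed as methylated over all reads, in Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1, Numba 0.67.0, PyArrow 21.0.0 and Matplotlib 3.10.9. The global level used autosomal CpG cytosines with at least 10 reads in both libraries, with a jackknife error over 10-Mb blocks. Single CpG dinucleotides (strands pooled, at least 10 reads), fixed 1000-bp tiles (at least 5 CpGs of at least 5 reads) and gene regions were tested by the two-sided Fisher's exact test with Benjamini-Hochberg adjustment. Dinucleotides and tiles were taken from the autosomes, and gene regions needed at least 5 CpGs of at least 5 reads. A call needed an adjusted p under 0.05 and a difference of at least 25 points for dinucleotides, 15 points for tiles and 10 points for gene regions. Differences are DEHP minus control in percentage points, with 95% Newcombe intervals, and levels with Wilson intervals in place of the planned exact binomial ones. Intervals cover counting error only, since PCR reads are not independent molecules and CpGs on 1 read are not independent.

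Gene names and extents came from a RefSeq table for GRCh38.p14. Its patch differs from that of the files. The table was used only to decide which CpGs lie in or near a gene, and all printed positions are CpG or tile positions from the files. The table holds no strand and no exons, so a gene's start cannot be placed. The planned promoter windows were replaced by windows of 1000 bp to each side of both ends of each protein-coding gene record, called gene-end windows, and by gene bodies. Each gene-end window is named as the lower-coordinate or upper-coordinate end. Exon, UTR, CpG island and repeat classes were not analysed here. As a check of positions, the control level within 500 bp of gene ends was 81.2%, against 84.2% at points shifted by 20 kb.

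The choices of tests, alternatives and gene lists were made before the data were examined, apart from those named as added. The 20 gene lists hold 651 entries, and all 651 matched the table. The planned promoter medians could not be computed, so gene bodies, planned as an alternative, served as the main measure. Each list's median gene-body difference was placed among 10000 random lists of protein-coding genes matched on level and CpG number. Named gene-end windows are the 12 largest gains and 12 largest losses among calls in which both strands differed the same way by at least 5 points, with the window of more CpGs kept where windows overlap. Named tiles are the 6 largest gains and 6 largest losses under the same strand rule. From each list, up to 4 called members, or the 2 largest differences where none was called, are given as values, as are DNMT1, DNMT3A, DNMT3B, UHRF1, TET1, TET2, TET3 and PPARA. Some members named by this rule are not reported here.

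Alternatives were other coverage minimums, difference thresholds, tile, window and bin sizes, unweighted means, thinning of the DEHP library by a factor of 0.914 to the control depth with the listing rule applied again, correction for background, and an overdispersion factor. Alternatives added after seeing the data were depth matching at each site, weighting sites by the smaller depth, leaving out sites of 100 or more reads, keeping CpGs at least 400 bp apart on each strand with at least 2 CpGs per region, an overdispersion factor from the libraries, and the settings for gene bodies. The comparison of calls from 1 strand with the other strand was also added then, as were the swap of control and DEHP on the minus strand alone and the count of listed CHH cytosines with DEHP thinned to the control depth. The called gene bodies other than APOA1 lie outside the naming rule and were named after their values were seen.

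The tests were tested on simulated reads drawn independently at the real depths and levels with the listing rule applied, with 200 regions of each kind lowered by known amounts. Of the regions still measured, a fall of 20 points was recovered in 45% of 40 tiles (1231623 tested), 78.7% of 47 gene-end windows (31565 tested) and 94% of 50 gene bodies (19076 tested). For dinucleotides (11578709 tested), a fall of 80 points was recovered in 30% of 30 and falls of 40 points in 0 of 50. Unchanged regions apart from the changed ones gave 14 calls among gene-end windows, 4 among gene bodies, 3 among tiles and 0 among dinucleotides. The simulated reads carry no correlation between CpGs of 1 molecule, so these counts leave that source of calls out.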

Results

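DNA methylation was measured at single cytosines in HepG2 hepatocarcinoma cells without and with exposure to the plasticizer DEHP, with 1 library in each group. The series' title ties DEHP to lipid metabolism, autophagy and mitochondria, and the design asks how the methylome differs with exposure. At autosomal CpG cytosines listed in both libraries with at least 10 reads, the mean depth was 14.7 reads in control and 15.8 in DEHP. Relative depth per autosome was taken over cytosines listed in both libraries with at least 5 and under 100 reads. It was nearly the same in both libraries, though copy number itself was not measured. Chromosome 20 stood at 1.40 times the autosomal mean in control and 1.39 times in DEHP, and chromosome 4 at 0.760 and 0.751.

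Autosomal CpG cytosines listed in both libraries with at least 10 reads carried slightly less methylation in the DEHP library. Over 9358760 shared cytosines the level was 76.1% in control (95% Wilson interval 76.06 to 76.08) and 75.5% in DEHP (75.51 to 75.52), a difference of -0.554 points with a jackknife error of 0.0658 over 294 blocks. The level was lower in DEHP on 22 of 22 autosomes, from -0.320 points on chromosome 17 to -1.30 points on chromosome 16. Without sites of 100 or more reads, of which the autosomes held 9846, chromosome 16 differed by -0.485 points. Matching depth at each site left a global difference of -0.203 points, the unweighted mean of site levels differed by -0.260 points, and all sites of each file, shared or not, differed by -1.07 points.

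**Figure D1:**
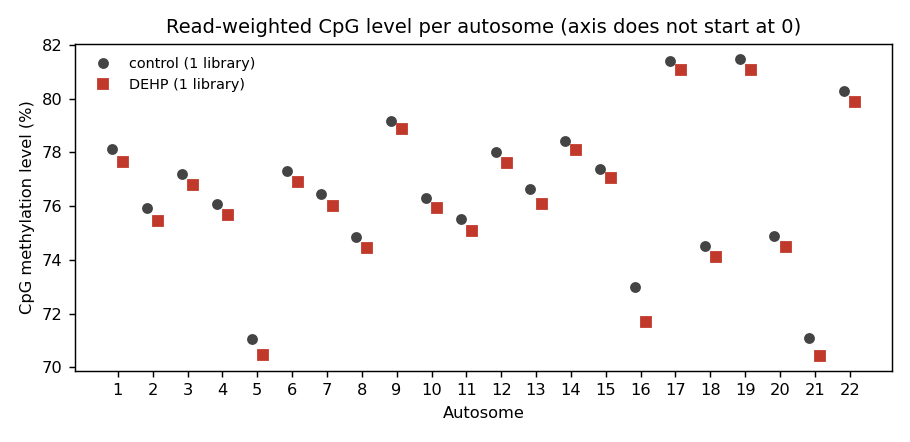
Read-weighted CpG methylation level (%, vertical axis, which does not start at 0) on each of the 22 autosomes (horizontal axis) in the control library (circles) and the DEHP library (squares), 1 library each, with no error bars. DEHP lies below control on all 22, with the widest gap on chromosome 16 (-1.30 points).

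Gene-rich and gene-poor sequence differed in how far the libraries stood apart. Within 1 kb of the ends of protein-coding genes the level was 81.4% in control and 81.3% in DEHP, a difference of -0.107 points (jackknife error 0.0329). Inside protein-coding genes it was 84.3% and 83.9% (-0.379 points, error 0.0130), inside lncRNA genes 72.7% and 72.1% (-0.617 points, error 0.0171), and outside every gene record 72.6% and 71.9% (-0.657 points, error 0.0154). The contrast narrowed at 10 or more reads, with -0.139, -0.331, -0.489 and -0.537 points in the same order. Unweighted means gave -0.193, -0.312, -0.486 and -0.482 points. These classes, and the bins of 100 kb, left out sites of 100 or more reads. Depth was not matched in them, so how far depth and the listing rule set the contrast was not tested.

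Broad domains of intermediate methylation, which cover much of the HepG2 genome, showed the same tilt. Of 27173 bins of 100 kb, 11053 had a mean level of 50 to 70%, and their median difference was -0.668 points, with 74.8% of bins lower in DEHP. The 15962 bins above 70% had a median of -0.356 points, with 74.0% lower, and the 158 bins of 30 to 50% a median of -0.683 points, with 69.6% lower. No bin lay under 30%. Across all bins, 92.7% differed by less than 2 points.

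No single CpG dinucleotide differed between the libraries. Of 12013841 tested by Fisher's exact test, 0 passed, and the smallest adjusted p was 1. At an unadjusted p under 0.05 and 25 points, 58864 were higher and 66084 lower in DEHP. With any difference, 157447 had an unadjusted p under 0.05 by the same test. They were 1.31% of those tested, fewer than that cut allows with no difference at all. Median depth was 18 reads in control and 20 in DEHP, and in simulated reads at these depths only 30% of falls of 80 points and 0 of 50 falls of 40 points were recovered.

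Among 1-kb tiles, 91 were higher and 84 lower in DEHP of 1279607 tested by Fisher's exact test, and 10 and 5 with an overdispersion factor from the strands. That factor (2.01) compares the plus with the minus strand within a library. The strand difference recurred in both libraries (correlation 0.480 over 597667 tiles), so the factor holds more than noise between libraries. Under the factor from the libraries (1.14), 57 were higher and 36 lower. The tiles named below are from the Fisher's exact test. Among calls with both strands differing the same way, the tile with the greatest gain, at chromosome 3:107431001-107432000 in the lncRNA gene LINC01990, rose from 38.9% of 36 reads to 87.2% of 47 (+48.3 points, 27.9 to 64.0). A tile in KCNIP3, which encodes a calcium-binding protein, at chromosome 2:95346001-95347000, rose from 26.1% to 58.0% over 44 CpGs with 636 and 333 reads. Tiles in LINC01991 (chromosome 3:187965001-187966000, 41.2% to 80.7%), CFAP46 (chromosome 10:132853001-132854000, 31.4% to 62.8%), SYT3 and C19orf81 (chromosome 19:50653001-50654000, 53.0% to 81.2%) and BRF1 and PACS2 (chromosome 14:105301001-105302000, 45.7% to 73.2%) rose as well. The greatest loss lay in RBFOX1, which encodes a splicing regulator, at chromosome 16:6136001-6137000, where the level fell from 71.4% to 27.7% with 119 reads in each library (-43.7 points, -54.0 to -31.4). Levels also fell in the T cell receptor gamma locus TRG (chromosome 7:38274001-38275000, 70.3% to 36.2%) and at SNRPA1 (chromosome 15:101295001-101296000, 64.4% to 31.2%). In tiles with no gene record, levels fell at chromosome 1:30695001-30696000 (85.2% to 47.5%), chromosome 20:22726001-22727000 (79.6% to 43.8%) and chromosome 21:22159001-22160000 (80% to 47%). Tiles called on the plus strand alone (188) differed there by 24.1 points on average, and by -0.373 points in the same direction on the minus strand (error 0.684), which comes from other molecules. With control and DEHP swapped on the minus strand alone, 165 tiles were called, against 175 as deposited. Calls with both strands at least 5 points the same way numbered 119 after the swap, against 129 as deposited. The swap breaks any change shared by both strands, so agreement of the strands says little for a named tile. Over the 597667 tiles, the differences on the plus and minus strands correlated at 0.00404. With DEHP thinned to the control depth 6 of the 12 named tiles lost their call with nearly the same difference, among them LINC01990 (47.5 points). Of the 12 named tiles 11 had no value with at least 10 reads per CpG, and the tile at SYT3 and C19orf81 lost its call (35.8 points).

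**Figure D2:**
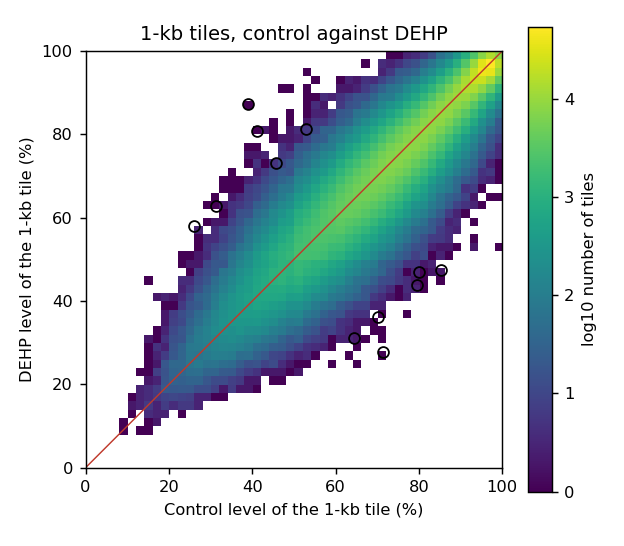
Methylation level of 1-kb tiles in control (horizontal axis, %) and DEHP (vertical axis, %), 1 library each, coloured by the log10 number of tiles per cell of the grid. The line marks equal levels, open circles mark the 12 named tiles, and 93.4% of tiles differed by less than 10 points.

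At the ends of protein-coding genes, 54 windows were higher and 56 lower in DEHP of 32054 tested by Fisher's exact test, and 11 and 2 with an overdispersion factor from the strands. As for tiles, that factor holds strand differences shared by both libraries. The forkhead transcription factor gene FOXP2 rose from 52.2% to 70.1% at its lower-coordinate end (chromosome 7:114085354-114087302, 87 CpGs, 1183 and 1172 reads; +17.9 points, interval 14 to 21.7; adjusted p = 1.72e-14, Fisher's exact test). With at least 10 reads per CpG the same FOXP2 window differed by -1.65 points. NKX6-1, a homeobox gene of pancreatic and neural development, rose from 53.5% to 71.0% (chromosome 4:84498303-84500182, 561 and 563 reads). The NKX6-1 window differed by 37.1 points with at least 10 reads per CpG and by -6.62 points with CpGs at least 400 bp apart. STX16, a syntaxin of the trans-Golgi network, rose from 44.5% to 70.2% (chromosome 20:58650304-58650464), and CYP4F22, a cytochrome P450 fatty acid hydroxylase, from 44.8% to 71.7% (chromosome 19:15551331-15553014). Gains were also called at TMEM59L (46.3% to 78.8%, 80 reads in each library), TDRP (46.3% to 74.4%), LRRIQ1 (23.2% to 45.4%), NPY4R2 (46.3% to 67.7%), SERAC1 (64.0% to 84.0%), GLRB (50.7% to 70.7%), RABEPK (43.5% to 63.4%) and SLAIN1 (41.7% to 60.1%).

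Among losses at gene ends with both strands differing the same way, the largest was at TBCCD1, which fell from 74.6% of 63 reads to 42.2% of 64 (chromosome 3:186569561-186569619; -32.4 points, -46.9 to -15.3). GSTA4, a glutathione transferase that handles lipid peroxidation products, fell from 62.1% to 39.0% (chromosome 6:52994284-52996262, 282 and 213 reads; adjusted p = 0.000425, Fisher's exact test). SNRPA1, a U2 spliceosome component, fell from 63.2% to 33.3% (chromosome 15:101295681-101296190), in a window that overlaps the SNRPA1 tile named above. VPS11, a subunit of the complexes that tether endosomes and lysosomes, fell from 77.4% to 58.2% (chromosome 11:119067026-119068773). Levels also fell at UBE2V1P16 (89.5% to 59.4%), TLE7 (61.7% to 36.7%), TGFB1I1 (89.7% to 65.5%), HTR1B (77.9% to 53.7%), MPLKIP (58.5% to 37.2%), CRIP1 (72.8% to 54.0%), CACYBP (69.6% to 53.7%) and LAMB3 (58.9% to 43.6%). Windows called on the plus strand alone (113) differed there by 17.6 points on average and by 0.747 points in the same direction on the minus strand (error 0.733). With control and DEHP swapped on the minus strand alone, 102 windows were called, against 110 as deposited. With DEHP thinned to the control depth, 10 named windows lost their call, TMEM59L (29.0 points) and TBCCD1 (-31.3 points) among them, and 18 kept it. With at least 10 reads per CpG 5 kept their call, 8 lost it, among them GSTA4 (-18.2 points), LRRIQ1 (17.0), VPS11 (-17.3), CACYBP (-13.3) and LAMB3 (-15.4), 2 turned their direction and 13 had no value.

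Over whole gene bodies, 5 genes were higher and 9 lower in DEHP of 19113 tested by Fisher's exact test. The median difference over all bodies was -0.283 points, the background for the counts of lower and higher genes below. APOA1, the main protein of high-density lipoprotein, rose from 48.9% to 67.3% (chromosome 11:116835766-116837613, 43 CpGs, 705 and 551 reads; +18.4 points, 12.9 to 23.7; adjusted p = 2.09e-07, Fisher's exact test). With at least 10 reads per CpG, APOA1 differed by -8.25 points, and with CpGs at least 400 bp apart by 2.66 points. CLEC11A (40.6% to 60.6%), NPY4R2 (48.5% to 62.8%), LENG9 (53.4% to 64.9%) and BEX2 (67.4% to 79.5%) were the other gains. Losses were called at HSFX1 (94.0% to 62.7%, 50 and 67 reads), ZIC2 (75.3% to 52.1%), ZNF580 (57.0% to 39.3%), FOXD4L3 (90.1% to 75.5%), ATP6V1G2 (68.5% to 55.2%), HCRT (66.8% to 55.1%), KRTAP10-2 (59.1% to 48.0%), SMIM10L2A (74.8% to 64.2%) and EPOP (72.6% to 62.2%). Swapping control and DEHP on the minus strand alone left 8 called bodies, against 14 as deposited. Both strands differed the same way by at least 5 points in 3 of these 8, against 9 as deposited. Called on the plus strand at 5 points, 70 bodies differed on the minus strand by 0.471 points in the same direction (error 0.403). Called on the minus strand, 63 differed on the plus strand by 0.0436 points (error 0.418). The swap rests on few calls and decides nothing alone. With CpGs at least 400 bp apart 0 gene bodies were called, with differences that shrank in some genes and not in others. CLEC11A then differed by 5.30 points, NPY4R2 by 8.82, BEX2 by 3.94, LENG9 by 1.88, ZIC2 by -5.44, ATP6V1G2 by -2.73 and EPOP by 8.29 points. FOXD4L3 differed by -20.9 points, KRTAP10-2 by -18.0, SMIM10L2A by -11.0 and HCRT by -10.9 points. With at least 10 reads per CpG 0 of the 14 called bodies kept their call (5 lost it, 1 turned and 8 had no value), and with DEHP thinned to the control depth 5 lost it: BEX2 (7.91 points), ZIC2 (-19.8), ZNF580 (-16.2), HCRT (-9.69) and SMIM10L2A (-9.37).

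The enzymes that write and remove DNA methylation had like gene-body levels in both libraries. The maintenance methyltransferase DNMT1 stood at 95.3% in control and 95.5% in DEHP (difference 0.161 points, -0.372 to 0.697), DNMT3A at 92.1% and 91.9%, and DNMT3B at 91.7% and 92.0%. UHRF1, which recruits DNMT1 to newly copied DNA, stood at 93.8% and 93.7%. The dioxygenases TET1 (90.4% and 90%), TET2 (93.8% and 93.3%) and TET3 (91.7% and 91.6%), and the fatty acid receptor PPARA (92.6% and 92.4%), did not pass either. Of the 25 genes of the methylation machinery, 14 were lower and 11 higher, with 0 called bodies over all genes and 0 adjusted over the list alone. The largest differences were those of MAT2A, which makes S-adenosylmethionine (69.6% and 74.2%), and the DNA glycosylase gene MBD4 (85.2% and 89.0%).

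Lipid genes were mostly uncalled. Among 32 PPARA targets and fatty acid oxidation genes, 23 were lower and 9 higher in DEHP, with 0 calls over all genes and 0 adjusted over the list alone. CYP4A11, a fatty acid omega-hydroxylase, stood at 54.8% and 59.0%. The list's median was -0.267 points, at percentile 42.8 of random lists. It was -0.687 points at percentile 1.93 with at least 10 reads per CpG, but 0.656 points at percentile 94.8 in gene-end windows. Of 34 fatty acid, triglyceride and cholesterol synthesis genes, 24 were lower and 10 higher with 0 calls (median -0.190 points). The desaturase gene FADS1 stood at 93.7% and 95.5%, and GPAM at 87.3% and 86.0%. Of 35 lipid droplet, lipolysis and lipoprotein genes, 20 were lower and 15 higher (median -0.452 points), and 1 body, APOA1, was called both over all genes and adjusted over the list alone. The window at the lower-coordinate end of APOA1, which overlaps the gene body and shares CpGs with it, rose from 62.9% to 76.3%. That window differed by -1.73 points with at least 10 reads per CpG. Among the 66 end windows of this list, 1 was called over all genes and 2 adjusted over the list alone.

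Autophagy and mitochondrial genes gave 0 called bodies, over all genes and adjusted over the list alone. Of 41 core autophagy genes, 24 were lower and 17 higher, with a median of -0.167 points. GABARAP stood at 62.5% and 67.6% and GABARAPL2 at 91.8% and 93.8%. Of 32 measured lysosome, TFEB and mTORC1 genes, 24 were lower and 8 higher (median -0.217 points, percentile 51.7 of random lists), with DDIT4 at 30.5% and 26.3%. The end window of HEXA, a lysosomal hexosaminidase, fell from 67.0% to 56.4% (adjusted p = 0.0497, Fisher's exact test), which was 1 call among 49 windows. With DEHP thinned to the control depth the call at HEXA was lost (adjusted p = 0.116, Fisher's exact test), and with at least 10 reads per CpG the difference was -3.85 points. The 29 mitochondrial dynamics and mitophagy genes had a median of -0.213 points, with PHB2 at 88.2% and 89.6% and TWNK at 89.9% and 91.4%. The 38 nuclear-encoded respiratory chain genes had a median of -0.223 points, with COX6A1 at 73.8% and 81.4% and NDUFA2 at 80.3% and 76.6%. In gene-end windows the medians were -0.729 points for autophagy, 0.572 points for lysosome genes and 0.185 points for the respiratory chain, all inside the central 95% of random lists.

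Liver genes included APOA1 among the called members. Of 34 hepatocyte identity genes, 21 were lower and 13 higher, with APOA1 as the 1 called body over all genes and adjusted over the list alone. Of the 54 end windows of this list, 2 were called over all genes and 2 adjusted over the list alone. Of 34 xenobiotic receptors and enzymes, 20 were lower and 14 higher with 0 calls, including CYP2C8 at 66.8% and 58.8% and GSTT2 at 88.5% and 84.7%. The 29 genes of the steroid and hormone receptor list had a median of -0.668 points, at percentile 6.43. That list also holds the steroid enzyme genes HSD3B1 (52.6% and 62.8%) and HSD17B1 (76.6% and 81.9%). The 28 measured oxidative stress, NRF2 and apoptosis genes had a median of -0.138 points, with GPX4 at 49.4% and 33.3% and XBP1 at 86.0% and 91.7%.

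Developmental transcription factors had 4 bodies past the adjusted p, the most of the 20 lists, while 498 of 19113 bodies passed it over all genes. Of 42 genes, 22 were lower and 20 higher, and the list's median was -0.0236 points at percentile 96.3 of random lists. The 4 bodies did not reach 10 points, among them NKX6-1 (71.1% and 79.6%) and HOXA13 (52.1% and 60%). The NKX6-1 body, which overlaps the called window at its upper-coordinate end, differed by 34.8 points and was called with at least 10 reads per CpG. The lower-coordinate end of HOXA10 fell from 60.5% to 39.6%, though its strands differed by -29.4 and 4.36 points. The call at HOXA10 was lost with DEHP thinned to the control depth (-16.7 points) and with at least 10 reads per CpG (-19.9 points). Of their 77 end windows, 2 were called over all genes and 3 adjusted over the list alone. The remaining lists had 0 called bodies, both over all genes and adjusted over the list alone. The 32 measured germline and cancer-testis genes had the lowest median of the 20 lists, -0.905 points at percentile 2.81, with SSX2 at 41.8% and 53.3% and MAGEA3 at 68.3% and 60%. Imprinted genes had a median of -0.0105 points at percentile 96.7, with NAP1L5 at 61.0% and 56.3% and DIRAS3 at 81.1% and 77.0%. Tumour suppressors methylated in liver cancer had a median of -0.0963 points, with GSTP1 at 91.9% and 89.7% and SFRP2 at 78.9% and 76.9%. Markers of other cells stood at -0.399 points for blood (0 of 55 end windows called over all genes, 2 adjusted over the list alone), with GZMB at 72.9% and 84.7% and CD14 at 75.4% and 80.4%, and at -0.136 points for fibroblast, stellate and endothelial cells, with COL1A1 at 66.8% and 71.0% and CLEC4G at 80% and 77.0%. Housekeeping genes had a median of -0.422 points, with RPS18 at 48.7% and 45.2% and PSMB4 at 95.5% and 93.3%. Inflammation and interferon genes had a median of -0.508 points, with IRF7 at 85.7% and 92.0% and SAA1 at 74.7% and 68.5%. Of the 20 lists, 0 lay outside the central 95% of random lists in this setting. In gene-end windows the oxidative stress list had a median of 1.17 points (percentile 98.9) and the tumour suppressors one of -1.39 points (percentile 1.33). With at least 10 reads per CpG the germline list stood at -1.08 points (percentile 1.17) and the steroid receptors at -0.0512 points. Each of the 20 lists was placed in every setting, so some placements outside the central 95% are likely by chance alone.

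**Figure D3:**
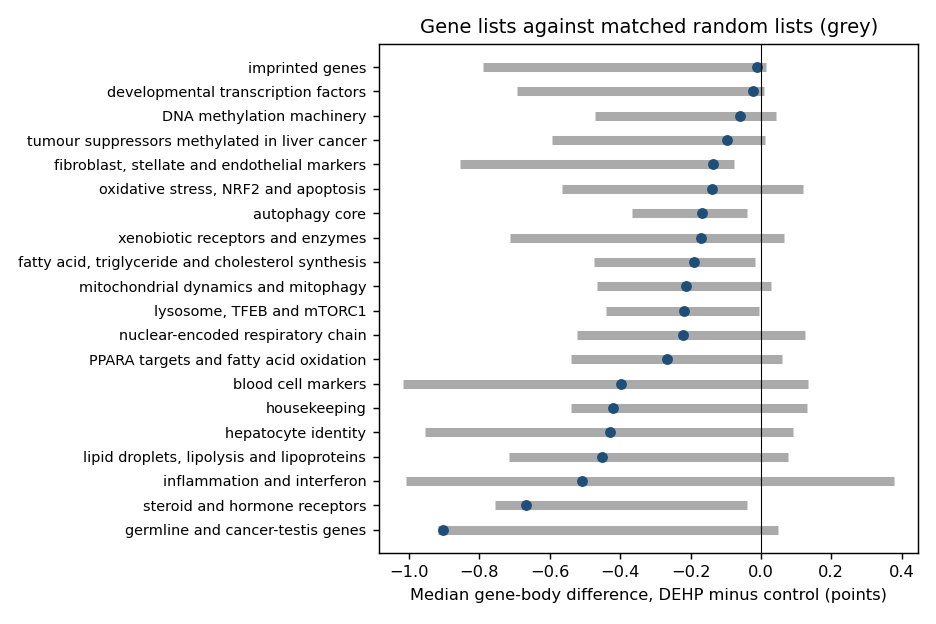
Median gene-body difference, DEHP minus control in points (horizontal axis), for each of 20 gene lists (points), with the central 95% of 10000 matched random lists (grey bars). All 20 medians are below 0 and inside the bars, from -0.905 points for germline genes to -0.0105 for imprinted genes.

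The mitochondrial genome differed more than any nuclear class measured here. On its plus strand, unconverted reads made up 12.6% at CpG, 12.6% at CHG and 13.1% at CHH cytosines in control, and 8.45%, 8.48% and 8.45% in DEHP. The share was lower in DEHP at 388 of 391 shared CpG, 467 of 469 CHG and 3676 of 3698 CHH cytosines, and the difference was -4.14 points at CpG (Newcombe interval -4.21 to -4.07). All 15 protein-coding and ribosomal RNA genes were lower on that strand, from -2.26 points in the ribosomal RNA gene RNR1 to -10.7 points in ND6, a subunit of respiratory complex I (22.4% and 11.7%). ND2 stood at 22.5% and 13.3%, COX1 at 11.7% and 8.11% and CYTB at 13.4% and 8.46%. On the minus strand the CpG share was 6.62% and 5.61%. Median depth at shared plus-strand CpGs was 3493 reads in control and 4253 in DEHP, and cytosines under 5% are missing from both files, so these shares describe listed cytosines only.

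**Figure D4:**
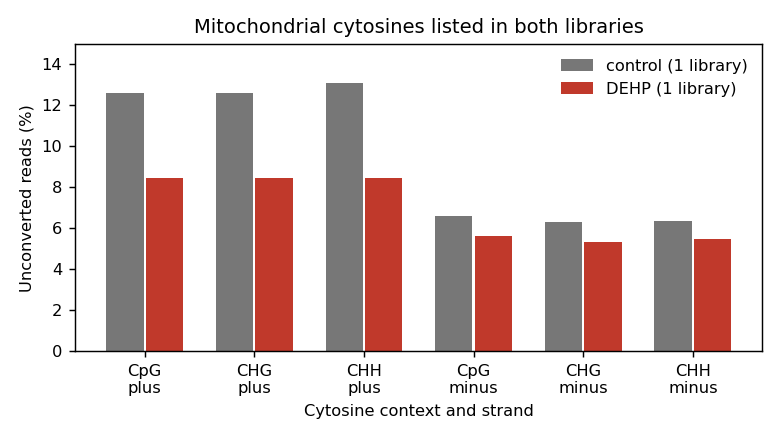
Unconverted reads (%, vertical axis from 0) at mitochondrial cytosines listed in both libraries, by context and strand (horizontal axis), for control (grey) and DEHP (red), 1 library each, with no error bars. On the plus strand control lies between 12.6% and 13.1% and DEHP at 8.45% to 8.48%, alike in all contexts.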

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

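This comparison was chosen after the files were seen. Outside the CpG measurement, more nuclear CHG and CHH cytosines were listed in the DEHP library than in the control library. On the autosomes 68407 CHG cytosines were listed in DEHP against 61730 in control, 47092 of them in both. For CHH the numbers were 187580 and 162724, with 118602 in both. Median levels at the shared CHG cytosines were 83.3% in control and 81.8% in DEHP, and at the shared CHH cytosines 80% in both. The DEHP library was also the deeper one, with a median of 11 reads against 10 at shared CHG cytosines. Thinned to the control depth, DEHP still listed 171874 CHH cytosines against 162724 in control (counting error 578). The thinning factor came from CpG cytosines listed in both libraries. Thinned DEHP also still listed more autosomal CpG cytosines alone, 5603631 against 4952752 in control alone. How far depth set the CHH excess therefore cannot be decided here. As a share of the cytosines tested, worked out from the deposited p-values over all sequences, the order turned. Of CHH, 0.713% were listed in DEHP and 0.835% in control, and of CHG 0.831% and 0.956%. The order turned because the number tested exceeded that of control by a wider margin than the number listed. In each library fewer CHH and CHG than CpG cytosines were tested. How the tested cytosines were chosen is not given in the sources used here. These shares therefore cannot be read as shares of all covered cytosines, or as less CHH or CHG methylation in DEHP.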

How the results depend on the processing

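No paired analysis was possible because each group has 1 library, and no library could be left out. The CpG island definition was not run because no genome sequence was used here, and promoter windows by strand were not run for want of strand. The settings with depth matched at each site, with sites weighted by the smaller depth, without sites of 100 or more reads, with CpGs at least 400 bp apart, with the overdispersion factor from the libraries and for gene bodies were chosen after seeing the data. The cause of each shift below was not tested except where named. The global difference kept its sign under every alternative: -0.260 unweighted, -0.565 at 5 reads or at 1 read, -0.577 at 20 reads, -0.452 with DEHP thinned, -1.07 over all sites of each file, -0.203 with depth matched, -0.255 with sites weighted by the smaller depth and -0.456 without sites of 100 or more reads. Dinucleotide calls stayed at 0 under every alternative. Tiles higher and lower numbered 44 and 47 at 2000 bp, 13 and 27 at 25 points, 47 and 45 at 10 reads, 10 and 5 with the strand overdispersion factor (2.01), 57 and 36 with the factor from the libraries (1.14), and 0 and 0 with spaced CpGs; lower tiles numbered 138 at 500 bp and 143 at 10 points. Gene-end windows numbered 95 and 89 at 5 points, 11 and 12 at 20 points, 17 and 20 at 10 reads, 11 and 2 with the strand factor, and 0 and 0 with spaced CpGs; lower windows numbered 35 with DEHP thinned and 36 unweighted. Gene bodies numbered 35 and 32 at 5 points, 1 and 2 at 20 points, 2 and 4 at 10 reads, and 0 and 0 with spaced CpGs. Spaced CpGs leave few reads: they recovered 4.26% of 47 simulated falls of 20 points among gene-end windows and 0 of 42 among tiles, so their 0 says little there; in gene bodies they recovered 90% of 50, though bodies had a median of 257 CpGs and the called ones 35. With spaced CpGs the GSTA4 window stood at -2.10 and the HOXA10 window at -2.19, the KCNIP3 tile at 33.2 and the RBFOX1 tile at -45.8, all without a call. Differences by class kept their sign: near gene ends -0.193 unweighted; inside protein-coding genes -0.331 at 10 reads and -0.312 unweighted; in lncRNA genes -0.489 and -0.486; outside genes -0.537 and -0.482. Bins of 30 to 50% stood at -0.482 in 200-kb bins and -0.432 at 10 reads, bins of 50 to 70% at -0.645 in 50-kb bins, -0.700 in 200-kb bins and -0.491 at 10 reads, and bins over 70% at -0.268 at 10 reads. List medians in gene-end windows were 0.656 (PPARA targets), -0.908 (lipid droplets), -0.729 (autophagy), 0.572 (lysosome), 0.185 (respiratory chain), 1.17 (oxidative stress, percentile 98.9), -1.23 (methylation machinery), -0.177 (steroid receptors), 0.448 (developmental factors), -1.39 (tumour suppressors, percentile 1.33) and 0.605 (blood). At 10 reads per CpG they were -0.687 (PPARA targets, percentile 1.93), -0.323 (methylation machinery), -0.0512 (steroid receptors), -1.08 (germline, percentile 1.17) and -0.387 (developmental factors). Named calls that changed sign at 10 reads per CpG were the FOXP2 window (-1.65), the APOA1 window (-1.73) and the APOA1 body (-8.25), and with spaced CpGs the NKX6-1 window (-6.62) and the EPOP body (8.29).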

Other observations

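Tests in this part chosen only after the results were seen are those across strands and across the 2 sides of a window, with spaced CpGs, on mitochondrial cytosines, on listed CHH cytosines, with depth matched, with sites weighted by the smaller depth and without very deep sites; for the swap of libraries on the minus strand, and for the 2 sides when called on the lower-coordinate side, the expected outcome was written down before the test was run.

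End windows of the methylation enzymes and of PPARA gave 0 calls. The lower-coordinate end of DNMT3B, a de novo methyltransferase, stood at 63.1% in control and 71.7% in DEHP (168 and 180 reads), and that of TET1 at 42.6% and 49.6%. The upper-coordinate end of DNMT3A stood at 87.7% and 80.5%, and the lower-coordinate end of PPARA at 41.8% and 44.7%.

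Some autosomal CpG cytosines were listed in 1 library only. There were 3968248 of these in control, with a mean level of 65.3%, and 6208174 in DEHP, with a mean level of 66.3%. Tiles with 10 or more such cytosines in 1 library and none in the other numbered 157 for control and 428 for DEHP, and 200 and 296 with DEHP thinned to the control depth.

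The called gene-end windows, such as FOXP2, STX16 and GSTA4, may reflect neighbouring CpGs read on the same molecules and counted as if independent. With control and DEHP swapped on the minus strand alone, which breaks any change shared by both strands, 70 windows were called with both strands at least 5 points the same way, against 79 as deposited. Windows called on the plus strand differed on the minus strand by 0.747 points in the same direction (error 0.733), and windows called on the upper-coordinate side differed on the other side by 0.121 points (error 1.08; -1.56 when called on the lower-coordinate side, error 1.09). These values argue against a change of whole windows in the exposed library as the source of most calls, though changes in single windows such as FOXP2 stay open. Calling 0 windows with CpGs 400 bp apart decides nothing for changes of about 20 points, since that setting recovered 4.26% of such simulated falls. It recovered 26.7% of falls of 30 points and 52.2% of falls of 40 points.

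Mitochondrial cytosines were unconverted less often in the DEHP library. Conversion of the whole library is argued against by the number of nuclear CHH cytosines listed. A fall of 4.64 points in every nuclear CHH cytosine would list at least 116453 more of them in control. Control minus DEHP thinned to its depth was -9150 (counting error 578). The reckoning takes covered CHH cytosines as no fewer than CpGs, which was not tested. The cytosines tested for the deposited p-values held fewer CHH than CpG. Methylation of CpGs is argued against, since the fall at CpG was smaller than at CHH (-0.495 points), and so are reads from nuclear copies, since the control level at CpG minus CHH was -0.495 points. Cytosines of mitochondrial DNA that escaped conversion in every context are a candidate explanation, since the fall spanned only 0.5004 points over the 3 contexts. Whether DNA preparation or the exposure set that difference was not tested, with 1 library in each group.

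The lower global CpG level in DEHP was weighed against 3 technical explanations. Depth matched at each site left -0.203 points (jackknife error 0.00623), and sites of 100 or more reads left out left -0.456 points (error 0.0219), so neither depth nor very deep sites could be the whole source. Weighting sites by the smaller depth, with no thinning, gave -0.255 points, so much of the drop under depth matching goes with the weights of sites. Incomplete conversion of control is argued against as the source of the full -0.554 points. It would list at least 16149 more nuclear CHH cytosines in control by the same reckoning, against -9150. Thinned DEHP still listed more CpG cytosines alone than control did, so the -9150 may hold some depth. No such number was worked out for the smaller differences of -0.203 and -0.255 points, so a part from conversion stays open there. Differences between cultures or libraries, and the exposure itself, stay open as untested.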
